A study of Homo sapiens with 6 samples.

How the data were processed

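Total RNA of RS4;11 cells was extracted with Trizol and a sequencing company built the libraries, per the labels. The labels name 3 samples with asparagine and 3 without it, and they give replicate numbers 1 to 3 in each arm. Nothing in them says that the samples of an arm came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. Per the submitters' processing notes, FastQC, STAR and featureCounts of the Subread package were used with the human build GRCh38. Tool versions, the gene annotation, the strand setting, the scaling method and the rule for dropping low genes are not given in the sources used here. Because no strand setting is stated, reads of a gene and of an antisense partner cannot be told apart.

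The deposited table holds normalized CPM, a depth-scaled signal per gene and library, with 11911 gene symbols in rows and 6 columns. Columns were matched to samples by the arm and the replicate number in their names, since the names are not the sample titles. The name used for the depleted arm may abbreviate asparaginase, and this could not be settled from the labels. In each column every value was a whole multiple of 1 step within a tolerance of 1e-06 of a read (100% of values), so the step is what 1 read is worth and the reads behind each value were recovered. The reads in the table ranged from 29971364 to 51127073 per library. Column totals were 1018766 to 1031234 CPM with asparagine and 918783 to 952458 in the depleted libraries, so the authors' divisor was not the total alone. A value of 3 reads corresponds to 0.0598 to 0.092 CPM per library. Every gene in the table reached at least 0.54 CPM in some library, so genes below that level are not in the table.

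Values were analysed in R 4.3.3 with limma 3.58.1 as log2(CPM + 1), since the table holds scaled values and not raw counts. Genes with at least 1 CPM in at least 3 libraries were kept, which left 11892. A linear model with the group as its only term was fitted over all 6 libraries, with empirical Bayes moderation and an intensity trend, and two-sided p-values were adjusted by the Benjamini-Hochberg method at a threshold of 0.05. Fold changes given as "-fold" are ratios of the group means in CPM, and log2 fold changes are the model's, depleted minus with asparagine. Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 30 lists with at least 5 tested genes. A total of 32 lists had been written from textbook knowledge before the data were examined. The same holds for the model, the panel of 6 genes and the rule for named genes. The rule took the panel, the 10 largest and 10 smallest log2 fold changes among genes past the threshold with at least 5 CPM in the higher group and no overlap between the groups, and up to 4 examples per list by size of change with at least 5 CPM in the higher group. Genes named beside these, wherever a list had 5 or fewer members of a kind, were chosen after their values were seen.

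Positions and GC content came from the GENCODE 29 annotation of GRCh38, whose build is the one the submitters name. GC content and length were medians over a gene's protein-coding transcripts, or over all its transcripts where it has none, and 95.4% of the genes in the table (11363) had a value. The GC correction removed, in each library, a lowess trend (span 0.3) of the deviation from the gene's mean over all libraries. It was chosen after the difference between depleted libraries had been seen.

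Alternatives fixed before the data were examined were pseudocounts of 0.25 and 4 CPM, no filter, a filter at 5 CPM, rescaling by an unweighted trimmed mean of log ratios or by median ratios, quantile normalization, moderation without a trend or robust, the replicate number as a block, each library left out in turn, a threshold of 0.01 and an estimated inter-gene correlation. Added afterwards were the GC correction, a GC and length correction, each library's GC slope as a covariate, the genes with a GC value alone, voom weights on the recovered reads, the GC correction with an estimated correlation, and fits without depleted libraries 2 and 3 or with the GC correction and without depleted library 1. The GC slope as a covariate was also combined with an estimated correlation, which is not counted in the ranges given over alternatives. No count model was used because the reads were recovered from scaled values.

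The model and the list test were tested on simulated data for this comparison of 3 against 3 libraries, over 11344 genes with 100 genes changed 2-fold and 100 changed 4-fold. With the spread measured per gene, 51% of 2-fold and 90% of 4-fold changes were recovered, and 4.08% of calls were false. With the GC correction on these data, recovery was 51% and 91%, and 4.70% of calls were false. With a simulated GC trend between libraries of one group, recovery was 66% and 100% without the correction and 100% and 100% with it, where 3.38% of calls were false. That run used a set gene spread, not the measured one, and held no GC difference between the groups. It therefore does not show how the correction performs on a GC difference between groups. In the real comparison 2987 of 11892 genes passed as higher and 3116 as lower, a far larger share than was changed in any simulation. The Benjamini-Hochberg threshold depends on that share, so the simulated recoveries do not carry over to the real comparison. The list test found the simulated changed list and called 0 of 20 unchanged ones. The simulated noise was independent between genes and the unchanged lists were random. This run therefore cannot show how often the preset correlation passes lists of genes that vary together. Pairs of libraries within a group differed by more than counting error, with a chi-square per gene of at least 5.48, so no library was counted as a duplicate. The lowest value was that of depleted libraries 2 and 3. It was 14.3 to 39.1 with asparagine, and 285 and 336 between depleted library 1 and depleted libraries 2 and 3. This cannot tell separate cultures from separate libraries of the same RNA. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.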

Results

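RNA levels were measured by RNA sequencing in RS4;11, an established human line of B-cell precursor acute lymphoblastic leukemia that carries the KMT2A::AFF1 fusion gene. By the sample titles, 3 libraries came from cells with asparagine and 3 from cells without it, and the series places RNA collection 16 hours after asparagine was removed. Asparagine is an amino acid that many lymphoblastic leukemia cells take up from their surroundings, and its removal from the blood is the principle of asparaginase treatment. The same medium, lacking asparagine and made with dialyzed serum, is entered for all 6 samples, so it is not stated whether the cells with asparagine also received dialyzed serum. The columns of the depleted arm carry a short name that could stand for asparaginase, and those of the other arm one that could stand for untreated. All column names share a prefix that could stand for control. The titles speak only of the presence or absence of asparagine. The arm without asparagine is therefore called asparagine-depleted here. The deposited table held 11911 genes. Its values corresponded to 36611101, 37400861 and 51127073 reads in libraries 1, 2 and 3 with asparagine, and to 40577308, 29971364 and 34590893 reads in depleted libraries 1, 2 and 3.

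Depleted library 1 stood apart from depleted libraries 2 and 3. Across genes, which are not independent replicates, Pearson's r of the log2 values was 0.940 and 0.933 between depleted library 1 and depleted libraries 2 and 3. It was 0.996 between depleted libraries 2 and 3, and 0.992 to 0.996 among the libraries with asparagine. The difference followed the GC content of the transcripts. With genes in 5 classes of about equal size by GC content, in the lowest class, depleted libraries 2 and 3 lay at medians of 0.81 and 0.87 on the log2 scale relative to the mean with asparagine, and in the highest class at -0.86 and -0.89. Depleted library 1 lay at 0.03 and -0.09 in those classes. Each gene list that passed its test is therefore given with its median after a GC correction as well. Of the ribosomal RNA symbols in the table, RNR2 took 0.24% to 0.271% of the values with asparagine, 0.424% in depleted library 1, and 0.551% and 0.559% in depleted libraries 2 and 3 (limma adjusted p = 0.00277). RNR1 and RNA45S5 had log2 fold changes of -0.07 and -0.83 and did not pass the test (adjusted p = 0.619 and 0.0567).

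**Figure D1:**
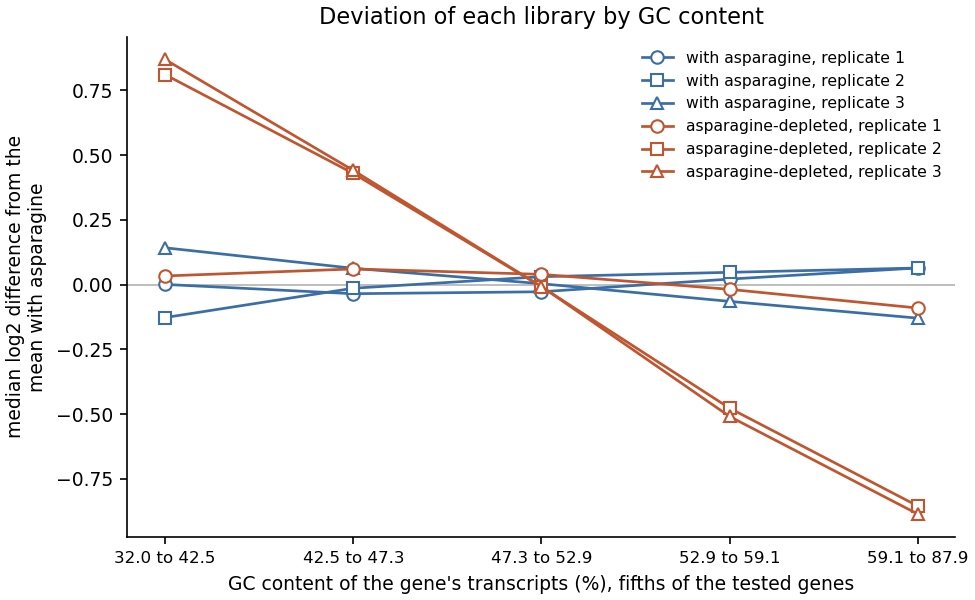
Median log2 difference of each library from the mean of the 3 libraries with asparagine (vertical axis) in 5 classes of transcript GC content in percent (horizontal axis), over 11344 genes. Depleted libraries 2 and 3 fall from 0.81 and 0.87 in the lowest class to -0.86 and -0.89 in the highest, while depleted library 1 stays between -0.09 and 0.06.

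The comparison of the groups asks how the transcriptome of these leukemia cells differs after asparagine is removed. By a gene list test with a preset correlation between genes (limma camera), depleted cells had higher RNA levels of genes of the ATF4 amino acid response, amino acid transporters, autophagy and lysosome genes, p53 target genes and a few histone genes. They had lower levels of genes for DNA replication, ribosome biogenesis, heat shock proteins, cholesterol and fatty acid synthesis, glycolysis, respiration and ribosomal proteins. With an estimated correlation 0 of 30 lists passed (1, the ATF4 list, when a GC correction was added) and 8 had an unadjusted p under 0.05, and the lists that had passed then had adjusted p-values from 0.0535 to 0.562. Asparagine synthetase, ASNS, was not among the genes that rose. Of 11892 genes tested, 2987 were higher and 3116 lower in the depleted cells (limma, Benjamini-Hochberg adjusted p under 0.05), 1278 and 1341 of them by at least 2-fold. The median log2 fold change of all genes was 0.01. Higher and lower are relative to the scaling of the libraries, so a change in total RNA could not be seen. The direction followed GC content, with 861 genes higher and 113 lower in the lowest GC class, and 154 and 1044 in the highest. Changes of single genes are given without the GC correction unless stated. It moved them either way, for example the log2 fold change of SLC7A11 from 4.39 to 3.62 and that of TRIB3 from 4.20 to 4.80.

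The size of these counts depended on single libraries. It was 4812 higher and 4913 lower without depleted library 1, 1902 and 1975 without depleted library 2, 1756 and 1845 without library 1 with asparagine, and 1728 and 1814 without library 2 with asparagine. After the GC correction, 3988 genes were higher and 3894 lower among 11344 with a GC value. These included 2563 of the 2987 and 2667 of the 3116, and 0 of them in the opposite direction. Some of the 2987 and 3116 have no GC value and could not be called here. An uncorrected fit to the genes with a GC value alone called 2814 higher and 2996 lower. After the GC correction 877 genes were lower by at least 2-fold.

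A panel of 6 genes was set in advance, and values are given as mean ± SD of normalized CPM over n = 3 libraries per group. Positions are those of the protein-coding genes on GRCh38 in GENCODE 29. DDIT3, which encodes the stress transcription factor CHOP (chromosome 12, 57516588 to 57521737), rose from 22.5 ± 0.960 to 233 ± 43.6, with a log2 fold change of 3.31 (SE 0.16, limma adjusted p = 5.17e-05). TRIB3, a pseudokinase gene induced by ATF4 (chromosome 20, 362835 to 397559), rose from 22.7 ± 3.08 to 441 ± 113, by 4.20 (SE 0.20, adjusted p = 5.56e-05). CHAC1, whose product degrades glutathione (chromosome 15, 40952962 to 40956519), rose from 7.14 ± 0.622 to 86.6 ± 29.8, by 3.38 (SE 0.24, adjusted p = 0.000209). MYC (chromosome 8, 127735434 to 127741434) fell from 659 ± 47.9 to 305 ± 54.7, with a log2 fold change of -1.12 (SE 0.15, adjusted p = 0.00166) and -0.66 after the GC correction.

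The other panel genes, ASNS and ATF4, did not pass the test. ASNS, which makes asparagine from aspartate and glutamine (chromosome 7, 97852118 to 97872542), stood at 11.2 ± 0.857 with asparagine and 8.77 ± 1.08 in depleted cells. Each depleted value (7.82, 8.55 and 9.95 CPM) lay below each value with asparagine (12.2, 10.8 and 10.7 CPM). The ASNS log2 fold change was -0.33 (95% interval -0.66 to 0.0126, adjusted p = 0.0943), on 279 to 535 reads per library. After the GC correction it was -0.63 (adjusted p = 0.00186), and the adjusted p ranged from 0.000373 to 0.281 over 23 alternative settings. ATF4, the transcription factor of the amino acid response (chromosome 22, 39519695 to 39522685), stood at 399 ± 21.02 and 489.6 ± 170.5, a log2 fold change of 0.24 (SE 0.23, adjusted p = 0.397). The 3 depleted libraries gave 686, 400.2 and 383 CPM for ATF4. The change was -0.027 without depleted library 1 (adjusted p = 0.715) and 0.55 after the GC correction (adjusted p = 0.00291). With the GC correction and without depleted library 1 it was 0.42 (limma adjusted p = 7.67e-06). The adjusted p ranged from 7.42e-07 to 0.715 over the alternatives.

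**Figure D2:**
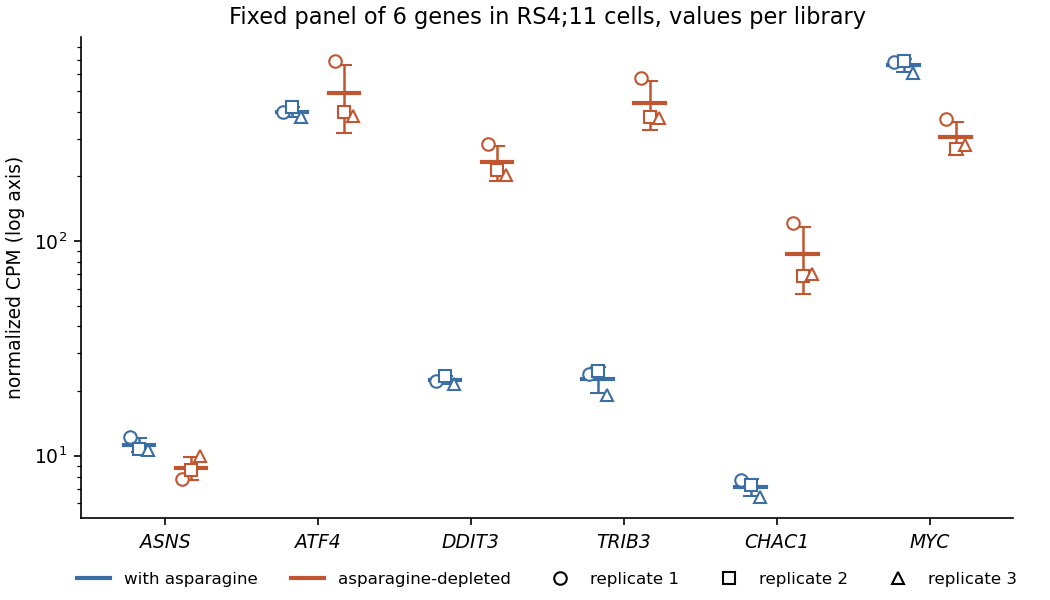
Normalized CPM (vertical log axis) of the 6 panel genes (horizontal axis) in each of the 6 libraries; symbols are replicates, thick bars the group means and thin bars ± 1 SD, blue with asparagine and orange depleted. DDIT3, TRIB3 and CHAC1 lie above every library with asparagine in all 3 depleted libraries, and MYC lies below. ASNS lies between 7.82 and 12.2 in all 6, with each depleted library below each library with asparagine. ATF4 overlaps between groups.

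Genes that ATF4 and its partners are known to induce when amino acids run short formed the group with the largest shift. Of 28 tested, 23 were higher and 0 lower (24 and 1 adjusted over the list alone), with a median log2 fold change of 2.83 (limma camera adjusted p = 5.23e-12, or adjusted p = 0.0535 with an estimated correlation). INHBE, a gene for an activin subunit (chromosome 12, 57452323 to 57459280), rose 97.8-fold from 0.622 ± 0.106 to 60.8 ± 17.3. FAM129A, the older symbol of the stress gene NIBAN1, rose 151-fold to 43.7 ± 5.14. STC2, encoding a secreted glycoprotein, rose 42.4-fold to 42.8 ± 3.61, and SLC7A11, the cystine-glutamate exchanger, 25.02-fold to 247 ± 112. The 5 members that did not pass were ASNS, ATF4, BCAT1, CTH and EIF4EBP1. Each depleted library showed the shift, with medians of 3.05, 2.58 and 2.59 in libraries 1, 2 and 3, and the median was 3.07 after the GC correction (adjusted p = 0.0441 with an estimated correlation, in a range of 1.25e-13 to 0.0535 over 25 alternatives). Outside these alternatives, with the GC slope as a covariate and an estimated correlation, the camera adjusted p was 0.116.

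The 10 genes with the largest increase included INHBE, FAM129A, STC2 and SLC7A11. The first by log2 fold change was JUN, a subunit of the AP-1 transcription factor (chromosome 1, 58780788 to 58784327), which rose 48.3-fold from 4.46 ± 0.493 to 216 ± 78.1, by 5.26 (SE 0.25, adjusted p = 5.14e-05). UNC5B, a netrin receptor gene, rose 54.3-fold to 69.0 ± 17.5, BEST1, a gene for a chloride channel, 154-fold to 23.2 ± 3.87, and GDAP1L1 96.2-fold to 25.04 ± 7.49. TMTC1 had 4 reads in all libraries with asparagine and 20.3 ± 7.68 CPM in depleted cells. ESRP1, a gene for an epithelial splicing regulator, had 0 reads in the 3 libraries with asparagine and 19.3 ± 4.21 CPM in depleted cells, which is at least 785-fold higher if 3 reads over the group are taken as the limit. Log2 fold changes were computed with 1 CPM added and understate the change of such low genes.

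Among the 10 genes with the largest decrease, ACOT7, an acyl-CoA thioesterase gene (chromosome 1, 6264269 to 6394391), fell from 255 ± 25.7 to 19.4 ± 5.96, with a log2 fold change of -3.69 (SE 0.22, adjusted p = 0.00012). UNG, the uracil-DNA glycosylase gene (chromosome 12, 109097574 to 109110992), was 10.6-fold lower at 17.6 ± 0.869. The nucleoside transporter gene SLC29A1 was 7.81-fold lower at 24.6 ± 2.89, the proteoglycan gene CSPG4 7.34-fold at 59.7 ± 24.5, and the mitochondrial nucleoside diphosphate kinase gene NME4 7.24-fold at 18.9 ± 11.0. HPDL was 8.57-fold lower, LRRC45 7.96-fold and LOC344967 11.8-fold. The remaining members, HSPB1 and HSPA8, are heat shock genes.

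All 13 heat shock and chaperone genes tested, cytosolic except for the mitochondrial HSPD1 and HSPE1, were lower (13 adjusted over the list alone), with a median log2 fold change of -2.03 (camera adjusted p = 7.65e-08, or adjusted p = 0.0535 with an estimated correlation) and -2.04 after the GC correction. HSPA8, the constitutive HSP70 (chromosome 11, 123057489 to 123063230), fell 7.47-fold from 2106 ± 102 to 282 ± 8.05 CPM. HSPB1, a small heat shock protein gene, fell from 1168 ± 116 to 149.7 ± 87.0, and HSPE1, the mitochondrial chaperonin partner, from 38.5 ± 8.46 to 5.77 ± 0.881. HSPA1B fell 7.04-fold, although its reads cannot be cleanly separated from those of its near-identical neighbour HSPA1A. A list of endoplasmic reticulum chaperones and of sensors, transcription factors and degradation genes of its stress response did not pass, with 9 of 21 higher and 9 lower (9 and 10 adjusted over the list alone, camera adjusted p = 0.961), a median of -0.16 and a mean of 0.20. Within it ERN1, which encodes the stress sensor IRE1, rose 23.8-fold to 71.0 ± 9.66, DNAJB9 5.19-fold and SEL1L 4.87-fold, while SDF2L1 fell 5.59-fold.

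Of 28 genes for DNA replication and the G1-to-S step, 27 were lower and 0 higher (28 lower adjusted over the list alone). Their median log2 fold change was -1.39 (camera adjusted p = 3.65e-12, or adjusted p = 0.0535 with an estimated correlation) and -1.33 after the GC correction. UHRF1, which guides maintenance DNA methylation, fell 7.12-fold from 708 ± 37.6 to 99.4 ± 32.8, CCNE1, the gene of cyclin E1, 7.09-fold to 4.64 ± 1.60, and GINS2, part of the replicative helicase, 5.81-fold to 24.4 ± 1.27. The member that did not pass was POLA1. Of 29 genes of mitosis, 8 were higher and 2 lower (8 and 2 adjusted over the list alone), and the list did not pass (median 0.28, camera adjusted p = 0.114; median 0.43 and adjusted p = 0.049 without depleted library 1, and 0.0314 to 0.81 over 25 alternatives). After the GC correction 10 of them were higher and 8 lower, with a median of 0.06 (adjusted p = 0.722). PRC1 and TPX2, which build the spindle, rose 2.11-fold and 2.09-fold, and the lower ones were CDC20 and KIF20A. The histone list had 6 tested genes, of which 5 were higher and 0 lower (5 adjusted over the list alone; median 1.03, camera adjusted p = 0.00939, or adjusted p = 0.296 with an estimated correlation; 1.12 after the GC correction). They were HIST2H2BE, HIST1H2AC, HIST1H2BD, HIST1H2BK and HIST1H1C, histone genes also known to give polyadenylated transcripts outside S phase.

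Ribosome biogenesis and other MYC-regulated growth genes fell together. Of 33 tested, 30 were lower and 0 higher (30 adjusted over the list alone), with a median log2 fold change of -1.13 (camera adjusted p = 1.75e-10, or adjusted p = 0.0535 with an estimated correlation) and -0.999 after the GC correction. NME1, a nucleoside diphosphate kinase gene, fell 6.86-fold from 118 ± 7.72 to 17.2 ± 6.79, MYBBP1A, encoding a nucleolar protein, 3.62-fold, and SRM, the spermidine synthase gene, 3.36-fold. The members that did not pass were DDX18, DDX21 and UTP20.

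Cytosolic ribosomal protein genes were lower in 41 of 76 tested and higher in 0 (46 lower adjusted over the list alone), with a median of -0.76 (camera adjusted p = 7.65e-08, or adjusted p = 0.562 with an estimated correlation). This shift was uneven between libraries, with medians of -0.14 in depleted library 1, -1.07 in library 2 and -1.15 in library 3, and it stayed uneven after the GC correction at -0.14, -1.01 and -1.05. Over all depleted libraries the median was -0.73 after the GC correction and -0.13 with each library's GC slope as a covariate (adjusted p = 0.0484, in a range of 3.41e-15 to 0.581 over 25 alternatives). Outside these, that covariate with an estimated correlation gave a camera adjusted p of 0.827. RPL8, the most abundant of the 4 examples, had 4042 ± 89.2 CPM with asparagine and 1436 ± 817 in depleted cells (adjusted p = 0.00832), and RPS15 had 356 ± 35.8 and 127 ± 120 (adjusted p = 0.0309). Reads of ribosomal protein genes are uncertain because many processed pseudogenes carry the same sequence. Nuclear genes of oxidative phosphorylation were lower in 28 of 34 and higher in 1, NDUFB5 (29 and 1 adjusted over the list alone). Their median was -0.86 (camera adjusted p = 1.37e-07, or adjusted p = 0.296 with an estimated correlation), from -0.50 in depleted library 1 to -0.97 and -0.99 in libraries 2 and 3. It was -0.81 after the GC correction, over the 28 members with a GC value, and -0.47 with the GC slope as a covariate. ATP5G1, encoding a subunit of the ATP synthase ring, fell 5.16-fold to 23.9 ± 6.18, and COX7B, of cytochrome c oxidase, 3.58-fold to 27.5 ± 3.87.

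Lipid synthesis genes were lower. Of 24 cholesterol synthesis genes, 17 fell and 0 rose (17 adjusted over the list alone), with a median log2 fold change of -1.11 (camera adjusted p = 1.55e-06, or adjusted p = 0.0535 with an estimated correlation) and -1.14 after the GC correction. MVD, an enzyme gene of the mevalonate pathway, fell 5.03-fold to 25.2 ± 12.03, DHCR7, which acts in the last steps, 4.81-fold to 22.5 ± 6.40, and LSS, which closes the sterol rings, 4.06-fold to 71.6 ± 22.0. Among 11 fatty acid synthesis genes, 8 fell and 2 rose (8 and 2 adjusted over the list alone; median -1.02, camera adjusted p = 0.00402, or adjusted p = 0.137 with an estimated correlation; -0.78 after the GC correction). FASN, the fatty acid synthase gene, fell 6.38-fold from 1289.9 ± 183 to 202 ± 71.9, and SCD, the stearoyl-CoA desaturase gene, 3.79-fold to 77.8 ± 4.86. The higher ones were ACSL3 and ELOVL6.

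Of 24 glycolysis and hypoxia genes, 16 were lower and 4 higher (16 and 5 adjusted over the list alone), with a median of -1.25 (camera adjusted p = 0.00371, or adjusted p = 0.412 with an estimated correlation) and -0.79 after the GC correction. The examples that fell were all enzymes of glycolysis. ENO1 fell 5.23-fold from 2016 ± 82.7 to 385 ± 77.2, PKM 4.77-fold from 3090.4 ± 162 to 648 ± 167, and GPI 4.44-fold to 143 ± 29.1. The 4 that rose, NDRG1, SLC2A3, KDM3A and BNIP3L, are known as hypoxia-responsive genes.

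Amino acid transporter genes were higher in 10 of 17 and lower in 1 (11 and 1 adjusted over the list alone), with a median of 0.71 (camera adjusted p = 0.00939, or adjusted p = 0.15 with an estimated correlation) and 0.90 after the GC correction. Besides SLC7A11, SLC6A9, a glycine transporter gene, rose 9.49-fold to 60.3 ± 17.4, and SLC38A2, a transporter of neutral amino acids including asparagine and glutamine, 3.14-fold to 711 ± 272. SLC38A5, another transporter of that family, fell 5.51-fold to 24.7 ± 7.24. Cytosolic aminoacyl-tRNA synthetase genes were higher in 11 of 20 and lower in 5 (11 and 7 adjusted over the list alone), which did not pass as a list (median 0.88, camera adjusted p = 0.0693; 0.023 after quantile normalization, the lowest of 25 alternatives, and 0.454 the highest). Their median was 0.61 after the GC correction. WARS, for tryptophan, rose 12.6-fold from 181 ± 0.541 to 2278 ± 74.2, GARS 3.24-fold and IARS 3.01-fold. The lower ones were FARSA, VARS, KARS, QARS and HARS. Enzyme genes of asparagine, aspartate and the urea cycle were split, with 5 of 17 higher (GOT1, ASS1, NARS, GPT2 and CPS1) and 4 lower (GOT2, CAD, GLUL and ADSL), the same numbers adjusted over the list alone, and a camera adjusted p of 0.958. GOT1, the cytosolic aspartate aminotransferase gene, rose 5.11-fold to 309 ± 20.6, while GOT2, its mitochondrial counterpart, fell 3.17-fold to 58.7 ± 1.78. Serine, one-carbon and proline genes were split as well, with 5 of 17 higher (PSAT1, MTHFD2, PSPH, SHMT2 and MTHFD1L) and 7 lower (5 and 7 adjusted over the list alone, camera adjusted p = 0.358). PSAT1 rose 3.57-fold, and SHMT1 fell 3.003-fold.

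Autophagy and lysosome genes were higher in 15 of 28 and lower in 3 (15 and 3 adjusted over the list alone), with a median of 0.41 (camera adjusted p = 0.0193, or adjusted p = 0.15 with an estimated correlation). MAP1LC3B, encoding the autophagosome protein LC3B, rose 5.58-fold to 268 ± 56.9, and WIPI1, which acts in autophagosome formation, 4.23-fold to 32.1 ± 1.57. The lower ones were ULK1, MCOLN1 and LAMP1. Among 24 p53 target genes, 11 were higher and 2, GADD45B and AEN, lower (11 and 2 adjusted over the list alone; median 0.61, camera adjusted p = 0.0301, or adjusted p = 0.154 with an estimated correlation). TNFRSF10B, a death receptor gene, rose 14.1-fold from 5.37 ± 0.0743 to 75.6 ± 3.45, and PMAIP1, which encodes the pro-apoptotic protein NOXA, 4.60-fold to 456 ± 135. BTG2 rose 2.67-fold and ZMAT3 2.24-fold, and PMAIP1 is also on the BCL2 family list. Whether p53 raised these genes was not tested. Without depleted library 1 the camera adjusted p was 0.056 for the autophagy list and 0.0615 for the p53 list, with ranges of 0.0055 to 0.15 and 0.00382 to 0.154 over 25 alternatives. Both medians were smaller after the GC correction, at 0.27 and 0.40. Of 19 glutathione and NRF2 genes, 11 were lower (11 adjusted over the list alone; median -0.68, camera adjusted p = 0.0317, or adjusted p = 0.296 with an estimated correlation; -0.44 after the GC correction). GPX1, a glutathione peroxidase gene, fell 2.62-fold to 184 ± 117, and the 2 that rose, SLC7A11 and CHAC1, are also on the ATF4 list. With each library's GC slope as a covariate this list's adjusted p was 0.0594, in a range of 0.0129 to 0.328 over the alternatives. Outside these, that covariate with an estimated correlation gave a camera adjusted p of 0.405.

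Of 31 genes that mark B-cell precursors, 13 were lower and 4 higher (13 and 4 adjusted over the list alone), with a median of -0.36 (camera adjusted p = 0.0317, or adjusted p = 0.154 with an estimated correlation) and -0.34 after the GC correction. VPREB1 and IGLL1, which form the surrogate light chain of the pre-B receptor, fell 3.64-fold from 438 ± 17.4 to 120.4 ± 42.9 and 3.33-fold from 854 ± 70.8 to 256 ± 139.8. The higher ones were PAX5, BACH2, POU2AF1 and FLT3. The camera adjusted p was 0.065 without depleted library 1, 0.0614 with a filter at 5 CPM and 0.24 after quantile normalization, the highest of 25 alternatives, of which 0.0113 was the lowest. Targets of the KMT2A::AFF1 fusion were higher in 10 of 26 and lower in 5, CSPG4, DOT1L, MEN1, ADGRE5 and HOXA7 (10 and 5 adjusted over the list alone), and did not pass as a list (median 0.33, camera adjusted p = 0.219). Myeloid markers had 6 tested genes, with CEBPA lower (camera adjusted p = 0.3), and T and NK cell markers had 5, with BCL11B higher and LCK lower (1 and 0 adjusted over the list alone, camera adjusted p = 0.961). Of the erythroid and stromal markers only COL1A1, ACTA2 and PDGFRB were in the table, and of the mitochondrial genome's messenger RNAs 0, so neither list was tested.

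The other lists did not pass the camera test. Immediate early genes were higher in 6 of 15 and lower in 3, DUSP2, JUNB and EGR1 (6 and 3 adjusted over the list alone; median 0.36, adjusted p = 0.225), and passed after the GC correction (median 1.10, adjusted p = 0.0234, or adjusted p = 0.143 with an estimated correlation). Their uncorrected median was 0.89 in depleted library 1 alone and 0.10 without it. Over the alternatives their adjusted p ranged from 0.0125 to 0.762, the highest with an estimated correlation. KLF6 rose 7.87-fold and KLF2 9.34-fold. Mitochondrial tRNA synthetase genes were lower in 8 of 17 and higher in 2, NARS2 and WARS2 (8 and 2 adjusted over the list alone; median -0.42, adjusted p = 0.0824), and passed after the GC correction (median -0.49, adjusted p = 0.0371). That was the lowest of the alternatives, and the highest was 0.517, with the GC correction and an estimated correlation. Interferon response genes were higher in 5 of 23 (XAF1, IFIT2, DDX58, IFIH1 and RSAD2) and lower in 8 (5 and 8 adjusted over the list alone, adjusted p = 0.462). BCL2 family genes were higher in 3 of 13 (PMAIP1, BMF and BCL2L2) and lower in 3, BID, BCL2L11 and BIK (3 and 3 adjusted over the list alone, adjusted p = 0.81). NF-kB genes were higher in 4 of 11 (TNFAIP3, TRAF1, ICAM1 and NFKB2) and lower in 3, IL1B, IER3 and NFKBIA (4 and 4 adjusted over the list alone, adjusted p = 0.869). DNA methylation enzyme genes were higher in 3 of 9 (TET2, IDH1 and TET3) and lower in 5, UHRF1, IDH2, DNMT1, TDG and DNMT3A (3 and 5 adjusted over the list alone, adjusted p = 0.284). WNT and GSK3 genes were higher in 1 of 7, GSK3B, and lower in 3, MYC, ZNRF3 and LEF1 (1 and 3 adjusted over the list alone, adjusted p = 0.152). The median and the mean of the NF-kB list and of the T and NK list differed in sign, at -0.05 and 0.14 and at -0.31 and 0.04. These medians were 0.13 and 0.15 in depleted library 1 alone and 0.05 and 0.15 after the GC correction, and that of the T and NK list was -0.54 without depleted library 1. In all, 15 of 30 lists passed with the preset correlation.

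**Figure D3:**
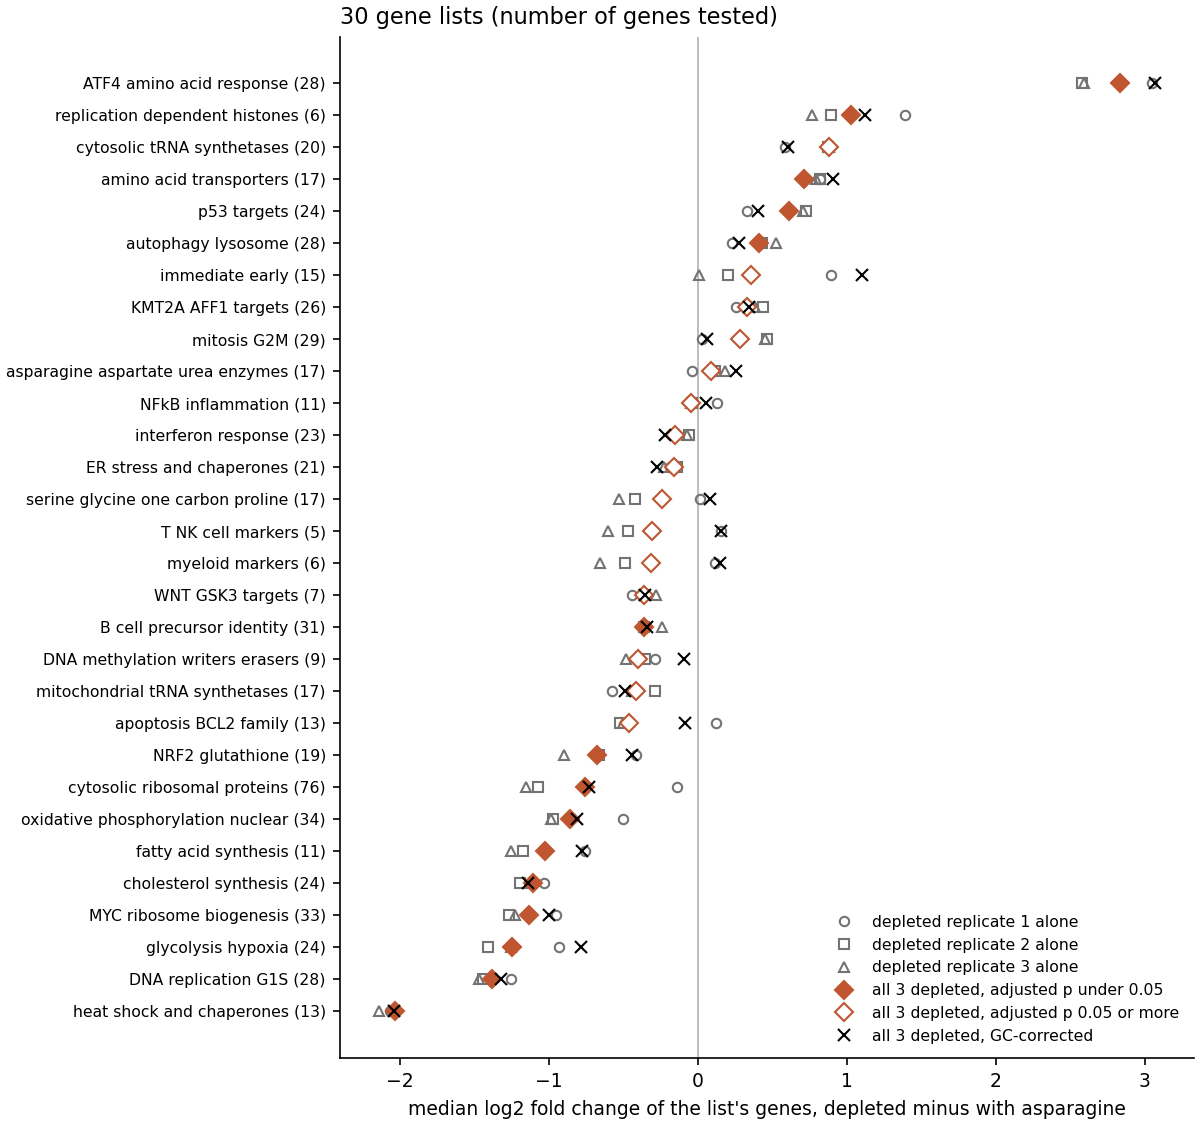
Median log2 fold change, depleted minus with asparagine (horizontal axis), of the genes of each of 30 lists (vertical axis, number of genes tested in brackets); filled diamonds passed limma's camera test with a preset correlation, open diamonds did not, crosses are the medians after GC correction and grey symbols the single depleted libraries. The ATF4 list lies at 2.83 and the heat shock list at -2.03, and the ribosomal protein list spreads from -0.14 in depleted library 1 to -1.15 in library 3.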

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

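The GC and length corrections, the GC slope as a covariate, the genes with a GC value alone, voom weights, the GC correction with an estimated correlation and the fits with a pair of libraries or a GC correction plus a library left out were chosen only after the results had been seen. With an adjusted p threshold of 0.01, 1612 genes were higher and 1703 lower. Leaving out each library in turn gave 1728 to 4812 higher and 1814 to 4913 lower, the most without depleted library 1. The number lower by at least 2-fold was 877 after the GC correction, 868 after the GC and length correction, 754 with the GC slope as covariate (804 higher) and 770 without depleted libraries 2 and 3. The other counts stayed within 1.5 times of those reported, and 47.6% to 50.6% of the genes called were higher in every setting. The libraries were scaled to each other in every setting, with a median log2 fold change of all genes from -0.0158 to 0.0442. The near-even split therefore cannot show whether total RNA changed. With the replicate number as a block, 2824 genes were higher and 2989 lower. Whether the numbers pair the libraries could not be decided. Within-group deviations of equal number correlated at 0.08, -0.65 and 0.69, and those of unlike number at -0.74 to 0.71. With an estimated correlation 0 lists passed and 8 had an unadjusted p under 0.05, 1 passed with an estimated correlation and the GC correction together, and 13 to 17 passed in the other settings. ATF4 reversed to -0.027 without depleted library 1, against up to 0.39 without another library. With the GC correction it was 0.42 without depleted library 1 (limma adjusted p = 7.67e-06), so the reversal was absent once the GC trend was removed. No other cause of it was tested. Of the other gene results under an alternative, 581 kept direction and side of the threshold and 11 passed it in the same direction, all of ASNS or ATF4. For the 15 lists that had passed, 340 results under an alternative kept both and 35 no longer passed, 29 of these with an estimated correlation, alone or after the GC correction. Of the lists that had not passed, immediate early genes passed in 5 alternatives, mitochondrial tRNA synthetases in 3, mitosis in 2 and cytosolic tRNA synthetases in 1. Counts of 3 reads, 0.0598 to 0.092 CPM, limit what could be detected.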

Other observations

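The gene families and the tests of GC content and GC slope, of RNA from the other group and of read number on ASNS were chosen only after the results had been seen. Beyond the lists fixed in advance, 16 gene families were defined by their symbols. Genes for subunits of the proteasome, which degrades tagged proteins, were lower in 20 of 37 and higher in 0, with a median log2 fold change of -0.53 (limma camera adjusted p = 0.000334, or adjusted p = 0.375 with an estimated correlation) and -0.52 after the GC correction. Genes for SR and snRNP splicing proteins were lower in 15 of 22 and higher in 0, with a median of -0.62 (camera adjusted p = 0.000641, or adjusted p = 0.375 with an estimated correlation) and -0.82 after the GC correction. Mitochondrial ribosomal protein genes were lower in 36 of 79 and higher in 3, with a median of -0.43 (camera adjusted p = 0.00029, or adjusted p = 0.409 with an estimated correlation), and RNA polymerase subunit genes were lower in 14 of 30 and higher in 2, with a median of -0.38 (camera adjusted p = 0.00655, or adjusted p = 0.409 with an estimated correlation). Their medians after the GC correction were -0.50 and -0.66. Tubulin genes, with those of the gamma-tubulin complex, were lower in 10 of 18 and higher in 1 (median -0.61, camera adjusted p = 0.00401, or adjusted p = 0.409 with an estimated correlation; -0.39 after the GC correction and -0.32 without depleted libraries 2 and 3).

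Numbered zinc finger genes, a large class of mostly KRAB-domain transcription factors, went the other way. They were higher in 133 of 364 and lower in 25, with a median of 0.42 (camera adjusted p = 0.000641, or adjusted p = 0.461 with an estimated correlation) and 0.28 after the GC correction (adjusted p = 0.00248). Without depleted libraries 2 and 3 the median was 0.17, with 94 higher and 45 lower. The other families did not pass the camera test, from CCT chaperonin subunits (6 of 11 lower and 2 higher, adjusted p = 0.0582), translation initiation factors (16 of 50 lower and 6 higher, adjusted p = 0.0702) and kinesins (10 of 29 higher and 5 lower, adjusted p = 0.0823) to MHC genes (4 of 20 higher and 5 lower, adjusted p = 0.902; 11 higher and 5 lower after the GC correction, adjusted p = 0.259). The remainder were nucleoporins (adjusted p = 0.226), RAB GTPases (0.227), Fanconi anaemia genes (0.454), snoRNA host genes (0.565), dual specificity phosphatases (0.565) and V-ATPase subunits (0.628). After the GC correction the CCT chaperonin, initiation factor, nucleoporin and Fanconi families passed as lower, with medians of -0.95, -0.37, -0.39 and -0.56 (adjusted p = 0.00303, 0.00236, 0.000575 and 0.0415, or adjusted p = 0.496, 0.465, 0.43 and 0.43 with an estimated correlation).

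The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 2987 genes higher, 3116 lower, and 1278 and 1341 by at least 2-fold, and the highest of the other splits gave 0 for each of these, so 1 of 10 splits reached each count. For gene lists, the real split gave 15 and the highest other 16, and 3 of 10 splits gave at least as many as the real split. Each of the other splits, however, puts libraries of both arms on each side. Part of the difference between the arms thus stays in the comparison, and the remainder adds to the spread within each side. Neither the gene counts nor the list counts of these splits can therefore decide whether chance would give the real counts.

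Depleted library 1 differed from depleted libraries 2 and 3 along the GC content of transcripts, and no biological explanation was tested because the design names none within a group. The GC correction removed 73.8% of the variance across genes of that difference (SD from 0.67 to 0.34). It was chosen after the trend had been seen and removes any difference that follows GC content, whatever its cause. The share removed therefore cannot tell a GC bias between libraries from another cause. A trend on GC content does not account for the ribosomal protein genes, which stayed 0.79 higher in library 1 after the correction (quartiles 0.51 to 1.13). RNA from cells with asparagine in library 1 is argued against, since a share of 81.9% would be needed and would put the 25 ATF4-list genes that rose, the same 25 with library 1 left out of the choice, at a median of -1.90, against a measured 0.00519, and all 28 tested at -1.84, against 0.00705. What separates the ribosomal protein genes of library 1 from those of libraries 2 and 3 stays open, and the RNR2 share also differed, at 0.424% against 0.551% and 0.559%.

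Ribosomal protein and oxidative phosphorylation genes were lower in depleted cells. A trend on transcript GC content as the whole cause is argued against by medians of -0.73 (57 of 76 genes lower, camera adjusted p = 1.49e-06) and -0.81 (26 of 28 lower, adjusted p = 3.84e-06) after the GC correction (adjusted p = 0.581 and 0.511 with an estimated correlation), and transcript length by -0.72 and -0.78 after the GC and length correction. A factor that varies between libraries with their GC slope stays open for both lists. With that slope as a covariate the oxidative phosphorylation median was -0.47 (24 of 28 lower, camera adjusted p = 3.54e-05, or adjusted p = 0.435 with an estimated correlation). The ribosomal protein median was then -0.13 (23 of 76 lower, camera adjusted p = 0.0484, or adjusted p = 0.827 with an estimated correlation). The slope was 0.21 in depleted library 1, -0.46 and -0.49 in depleted libraries 2 and 3, and 0.13 to 0.34 with asparagine. Both medians lay near those of depleted library 1 alone, -0.50 and -0.14. The fit thus rests mostly on 1 depleted library and cannot decide the question. A response to asparagine depletion may be the cause, but the ribosomal protein median was -0.14 in depleted library 1 against -1.07 and -1.15 in libraries 2 and 3, so another difference between libraries stays open. Reads shared with pseudogenes also stay open for the ribosomal proteins, since the deposited table holds no alignments.

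ASNS was not higher while most other ATF4-list genes rose. Too few reads is argued against, since 279 to 535 reads per library put the upper bound of its log2 fold change at 0.0126. GC content is argued against, since the corrected change was -0.63 (95% interval -0.89 to -0.36). No biological explanation for it was tested. Its group means of 11.2 and 8.77 CPM show that its RNA was present in both groups.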
